A study of Drosophila melanogaster with 10 samples.

How the data were processed

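RNA from Drosophila melanogaster S2 cells was measured on 10 Affymetrix 3' expression arrays. Per the labels' protocols, copper sulfate switched on the knockdown of SLIMP in stable lines, live cells stained with a DNA dye were sorted into G1 and G2/M fractions, RNA was taken with magnetic beads from small batches of sorted cells, and the cDNA was amplified by PCR and labelled with biotin. SLIMP is an insect mitochondrial protein related to seryl-tRNA synthetase, and its gene is Slimp. The labels gave 4 groups: control cells in G1 (n = 3), control cells in G2/M (n = 3), SLIMP knockdown cells in G1 (n = 2) and SLIMP knockdown cells in G2/M (n = 2). Control libraries were numbered 1 to 3 and knockdown libraries 2 and 3. Nothing in the labels said whether the numbers stood for separate cultures, so p-values measure the spread between these samples, which may be technical.

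The values were deposited by the authors as log2 probe set values made with RMA, per the submitters' processing notes. The version of RMA and any step after it were not given in the sources used here. RMA brings all arrays to 1 distribution, so a change shared by most transcripts of a library would not show. Array medians lay between 6.554 and 6.608 (log2). No further scaling was applied for the results in the report. Of 18952 probe sets, 183 array control probe sets were left out and 18769 were tested, with no filter on dim signal. The platform annotation gave 1 gene symbol to 13647 of these probe sets, several to 402 and none to 4720. Symbols were updated through the gene identifiers of RefSeq Release 6, which matched for 13544 probe sets and did not for 103. The named probe sets covered 11982 genes, of which 1094 had 2 or more probe sets. Genes were named only from probe sets with 1 symbol, and no genome sequence was used. The order of genes along each chromosome was taken from RefSeq for the comparison of neighbouring genes. No detection calls were used, so values near the bottom of the scale have only relative signal. Precision is limited by the number of arrays.

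Groups were compared with limma 3.58.1 in R 4.3.3. All 10 arrays entered 1 linear model with 1 coefficient per group and no replicate block. Contrasts were tested with moderated statistics (residual df 6, prior df 3.09), and p-values were adjusted by Benjamini-Hochberg over all 18769 probe sets at a threshold of 0.05. The contrasts were knockdown against control in G1, in G2/M and averaged over both phases, G2/M against G1 in control and in knockdown, and the interaction. The contrasts, gene lists, naming rule and most alternatives were fixed before the data were examined. A phase contrast over all 5 cultures, with culture as a fixed block, was added after the data were examined because it uses the genotype labels only to pair libraries.

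A culture here means the G1 and G2/M libraries that share a genotype label and a number. To check this pairing, deviations of each library from its group mean were correlated over all probe sets. They were 0.555, 0.514 and 0.685 for the cultures labelled control 1, 2 and 3, and 0.655 for both knockdown cultures, where groups of 2 force equal values. Every paired correlation was over 0.1, so the phase contrasts are also given with culture as a replicate block. That bound alone does not show the pairing, since some libraries of different cultures passed it too. G1 control 1 with G2/M control 2 gave 0.234, and G1 knockdown 2 with G2/M control 3 gave 0.517. Others were negative, such as G1 control 1 with G2/M control 3 (-0.504). Among control libraries, each G1 library correlated most with the G2/M library of its own number. Libraries of the 2 genotypes with the same number and phase correlated at -0.433, -0.661, -0.412 and -0.614. In knockdown groups of 2 libraries the 2 deviations are mirror images, so a control library must correlate with them at opposite signs. The negative signs for equal numbers went against a pairing of knockdown with control by number. With 2 mirrored libraries per group they cannot settle it. No 2 libraries of a group held identical values, with median absolute differences of 0.0894 to 0.176 (log2).

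Named genes followed a fixed rule. Slimp and SerRS-m came first. For each contrast, the 10 largest positive and 10 largest negative changes past the threshold were then named, where the libraries of the 2 groups did not overlap, with 1 probe set per gene (the smallest p). The overlap condition was dropped for the interaction and applied within each phase for the average. Where none passed, the 5 smallest p-values were named as not passing. For each gene list, up to 4 members past the threshold were named, or up to 2 with the smallest p where none passed. Other named genes were chosen after their values were seen and are marked so.

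The fixed gene lists numbered 27. Each gene was represented by its probe set with the highest mean, and lists with at least 3 measured genes were tested with limma's camera (2-sided, preset inter-gene correlation 0.01), adjusted over the 24 lists tested. Members past the threshold were counted over all probe sets and adjusted over the list alone. After the data were examined, the bare histone symbols were removed from the histone list because 1 of them resolved to the variant His2Av. That list then had 0 members measured by probe sets with 1 symbol, as had the list of mitochondrially encoded transcripts, and neither was analysed here. The list of Slimp and its synthetase partner had 2 members and got values only.

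The model was tested on simulated data with independent noise, real probe set means and known changes in 100 probe sets per fold size. At a log2 change of 1, the share recovered was 82% for knockdown against control in G1, 83% in G2/M and 95% for the average. It was 91% for phase in control, 79% for phase in knockdown, 60% for the interaction and 96% for phase over all 5 cultures. For the contrasts without a block, the simulated noise was independent between libraries. Those shares do not apply where the libraries of a culture vary together. For phase over all 5 cultures, the simulation added a difference between cultures. In simulated data, camera called the shifted list and 0 of the other lists. The noise there was also independent between genes. It therefore does not show how often camera calls a list whose genes vary together.

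Alternatives were the removal of probe sets with a mean below the median, cyclic loess, median centring, eBayes with trend and robust settings, array weights, a fit of only the groups compared, a fold threshold, 1 probe set per gene, several replicate blocks, culture means, and leaving out each library. For lists they were an estimated correlation, fry (directional and mixed), cyclic loess, a replicate block and the mean of all probe sets per gene. A crossed block, culture means for other splits and subsets of the cultures, the removal of pairs of cultures and the removal of each culture were added after the data were examined. Figures were drawn with matplotlib 3.10.9.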

Results

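The data were log2 signals of 18769 probe sets on 10 arrays of sorted Drosophila S2 cells, an embryonic cell line with haemocyte-like properties. Cells had been sorted in G1 or in G2/M from control cultures (3 libraries per phase) and from cultures carrying a copper-induced knockdown of SLIMP (2 libraries per phase). SLIMP is a mitochondrial relative of seryl-tRNA synthetase found in insects. Libraries are named below by their labels, and the G1 and G2/M libraries of 1 genotype label and number are called a culture.

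Slimp, the knockdown target, did not follow the genotype labels. Its probe set read 8.80 and 8.90 (log2) in the G1 and G2/M libraries labelled control 1 and 8.95 and 9.06 in those labelled control 2. In the libraries labelled control 3 it read 12.55 and 12.51, and in those labelled knockdown 2 it read 12.59 and 12.53. The libraries labelled knockdown 3 read 8.68 and 8.97. Group means were 10.10 ± 2.12 (SD, n = 3) for libraries labelled G1 control and 10.63 ± 2.77 (SD, n = 2) for those labelled G1 knockdown. They were 10.16 ± 2.04 (SD, n = 3) for G2/M control and 10.75 ± 2.51 (SD, n = 2) for G2/M knockdown. SerRS-m, the mitochondrial seryl-tRNA synthetase, lay between 9.76 and 10.37 in all 10 libraries. The metallothionein MtnA, a gene induced by copper, read 14.09 ± 0.08 (SD, n = 3) in G1 control and 14.07 ± 0.06 (SD, n = 2) in G1 knockdown libraries, close to the array maxima of 14.22 to 14.37. MtnB, with more room to move, read 11.19 and 10.11 in the G1 and G2/M libraries labelled control 1, 11.67 and 10.01 in control 2, 10.67 and 8.92 in control 3, 10.54 and 8.59 in knockdown 2, and 11.28 and 9.81 in knockdown 3. The part of the Slimp transcript that the probe set reads was not analysed here, so the values do not settle which level belongs to a knockdown. For this reason no direction is drawn from the genotype labels below.

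**Figure D1:**
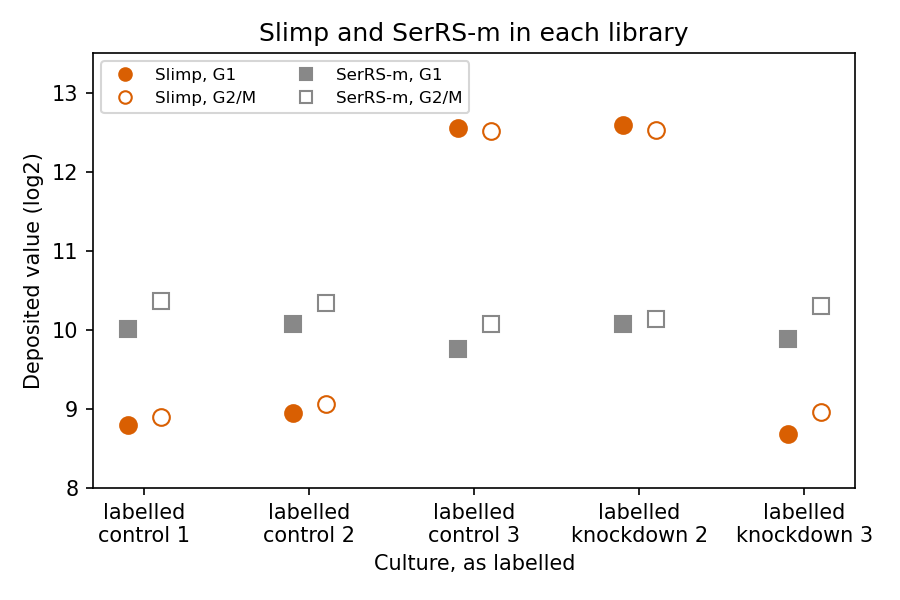
Deposited log2 values of Slimp (circles) and SerRS-m (squares) in each of the 10 libraries, by culture as labelled, with G1 filled and G2/M open. Slimp lies between 12.51 and 12.59 in the cultures labelled control 3 and knockdown 2, and between 8.68 and 9.06 in the other 3 cultures.

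Similarity over all probe sets also ran across the labels. The G1 library labelled control 3 was closest to the G1 library labelled knockdown 2 (r = 0.9976 over probe sets), and its correlations with the G1 libraries labelled control 1 and control 2 were 0.9884 and 0.9899. In G2/M, control 3 and knockdown 2 correlated at 0.9973. The G2/M library labelled knockdown 3 correlated at 0.9982 with control 1, 0.9975 with control 2 and 0.9930 with knockdown 2. Probe sets are not independent replicates, so these values carry no p.

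The first comparison asked which transcripts differed between libraries labelled knockdown and control in G1. No gene passed the threshold. The 5 genes with the smallest p were CG42335, ssp6, Muc96D, robl62A and Tsf1, and their differences were small. CG42335 was 0.46 ± 0.09 (SE) higher on the log2 scale in libraries labelled knockdown, at 4.82 ± 0.16 (SD, n = 2) against 4.36 ± 0.02 (SD, n = 3). The differences were 0.41 for ssp6, 0.45 for the mucin gene Muc96D, -0.44 for the dynein light chain gene robl62A and 0.41 for the iron transporter gene Tsf1, each with an adjusted p of 1 in limma. Slimp differed by 0.53 ± 1.70 (SE) and SerRS-m by 0.02. The sign for Slimp changed without the G1 library labelled knockdown 2 (-1.43), control 1 (-0.12) or control 2 (-0.05).

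Limma called 0 of 18769 probe sets in G1, and 482 (2.57%) had an unadjusted p under 0.05. None of the 24 gene lists was called with camera. The list with the smallest p was the proteasome, with a median of -0.07 and an adjusted p of 0.115. Without the cultures labelled control 3 and knockdown 3, a choice made after the Slimp values were seen, 363 probe sets passed (235 higher, 128 lower), with an unadjusted p under 0.05 for 3030. Without control 3 and knockdown 2, limma called 0, with 1251 at an unadjusted p under 0.05. Each of these 2 counts rests on 1 knockdown library, and the spread came only from control 1 against control 2.

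In G2/M, no gene passed between libraries labelled knockdown and control either. The 5 smallest p-values belonged to CG43155 (-0.32), CG12439 (-0.33), CG14304 (-0.30), the ciliary transport gene BBS1 (-0.34) and CG6262 (-0.25), all log2 differences with an adjusted p of 1 in limma. CG43155 read 5.26 ± 0.08 (SD, n = 2) in libraries labelled knockdown and 5.58 ± 0.07 (SD, n = 3) in those labelled control. Slimp differed by 0.59, and by -1.19 and -0.04 without the G2/M library labelled knockdown 2 or control 1. SerRS-m differed by -0.05.

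Limma called 0 probe sets in G2/M, and 164 (0.874%) had an unadjusted p under 0.05. No list was called. Glycolysis had the smallest p, with a median of 0.13 and an adjusted p of 0.278. Without the cultures labelled control 3 and knockdown 3, chosen on the Slimp values, 131 probe sets passed (74 higher, 57 lower), and without control 3 and knockdown 2 limma called 0, with 387 at an unadjusted p under 0.05. Here too 1 knockdown library was left, and the spread came only from the control libraries.

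Averaged over both phases, the genes with the smallest p were Muc96D (0.31 ± 0.07 SE), ssp6 (0.24), CG10177 (-0.27), CG34434 (-0.48) and robl62A (-0.26), and none passed. Slimp differed by 0.56, and by -0.42 and -0.33 without the G1 or G2/M library labelled knockdown 2. SerRS-m differed by -0.01. The lists with the smallest p were the proteasome (median -0.05), G2/M and mitosis (-0.04), glycolysis (0.12) and G1/S and DNA replication (-0.06), each with an adjusted p of 0.124 in camera. Limma called 0 probe sets for the average, with 267 (1.42%) at an unadjusted p under 0.05, and called 0 when each culture was first averaged to 1 value. Without the cultures labelled control 3 and knockdown 3, 861 passed (472 higher, 389 lower), and without control 3 and knockdown 2 limma called 0, with 1111 at an unadjusted p under 0.05. These fits took the 2 libraries of the 1 remaining knockdown culture as separate, and their spread came only from the control libraries. With each culture averaged to 1 value the counts were 436 and 0, the latter with 578 at an unadjusted p under 0.05.

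The interaction asked whether the labelled knockdown difference changed between phases. The smallest p-values were those of Tsf1 (-0.56 ± 0.13 SE), the immunoglobulin-domain gene beat-Vb (-0.49), the accessory gland protein gene Acp76A (-0.52), CG3769 (-0.40) and CG42335 (-0.46), each with an adjusted p of 1 in limma. Slimp gave 0.06, and from -1.89 to 2.02 when libraries were left out, and SerRS-m gave -0.07. Limma called 0 probe sets, with 333 at an unadjusted p under 0.05, and with culture as a paired block also 0, with 678. No list was called. Antioxidant and xenobiotic defence genes had the smallest p (median 0.08, adjusted p = 0.276 in camera).

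Across probe sets, the labelled knockdown differences in G1 and in G2/M correlated at r = 0.161 (Spearman's rho = 0.0687), and at r = 0.268 (rho = 0.122) in the upper part by mean signal. The other 9 ways of choosing 2 of the 5 cultures gave r between 0.228 and 0.736. Probe sets are not independent replicates.

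In libraries labelled control, mitotic genes were among those that rose from G1 to G2/M. The minus-end kinesin gene ncd rose 3.94-fold, from 9.37 ± 0.30 (SD, n = 3) in G1 to 11.35 ± 0.40 (SD, n = 3) in G2/M (adjusted p = 0.0242 in limma). The cyclin gene CycB3 rose 2.42-fold, the kinetochore gene Ndc80 by 1.16 on the log2 scale, and fzy, which encodes the Cdc20 activator of the anaphase-promoting complex, by 1.10. Of 79 genes for mitochondrial ribosomal proteins 7 passed, all higher in G2/M, among them mRpL2 (0.76), mRpL49 (0.75), mRpL9 (0.71) and mRpS35 (0.62).

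The largest rise was that of NANS, the gene for sialic acid synthase, at 5.17-fold (log2 2.37 ± 0.41 SE, adjusted p = 0.0408 in limma). The mitochondrial sirtuin gene Sirt4 rose 3.82-fold, CG15653 3.53-fold, the selenocysteine synthase gene SecS 3.13-fold and CG31125 3.10-fold. The replication clamp loader gene RfC3 rose 2.50-fold, the nuclear pore gene Nup35 2.39-fold and CG4570 2.37-fold. The largest fall was that of CanB, a regulatory subunit gene of calcineurin, from 8.30 ± 0.49 to 6.69 ± 0.38 (SD, n = 3 each), with an adjusted p of 0.0440 in limma. The odorant-binding protein gene Obp49a fell by 1.41 on the log2 scale, CG8620 by 1.29, the POU-domain gene pdm3 by 1.29 and the UDP-glycosyltransferase gene Ugt37D1 by 1.18. Rcd2 fell by 1.16, the Notch-modifying glycosyltransferase gene fng by 1.12, CG32024 by 1.07, CG32195 by 1.04 and CG34434 by 1.03. The adjusted p of these 20 genes lay between 0.0170 and 0.0498.

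Limma called 169 probe sets between phases in control (118 higher in G2/M, 51 lower). With culture as a paired block the count was 1678 (846 higher, 832 lower), and all 169 were among them. The block leaves the estimates, and so their direction, unchanged. With replicate number as a replicate block, limma called 0, with 2655 at an unadjusted p under 0.05. Limma called 0 when any of the 4 libraries labelled control 1 or control 2 was left out, with 1879 to 2484 at an unadjusted p under 0.05. Without the G1 library labelled control 3 the balance of directions reversed, with 68 higher and 85 lower. The count also fell without either G1 library labelled knockdown. It was the same for both by construction, because the 1 G1 knockdown library left is then fitted exactly.

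Of the gene lists, G2/M and mitosis genes shifted most in control. Their median log2 difference was 0.45, 13 of 65 measured members rose and none fell over all probe sets, 43 rose when adjusted over the list alone, and 36 rose with the paired block. Camera gave an adjusted p of 3.66e-22, against an adjusted p = 0.477 with an estimated correlation. Of mitochondrial ribosomal protein genes, 7 of 79 rose (median 0.28), and adjusted over the list alone 35 rose and 2 fell. Camera gave an adjusted p of 7.32e-16, with adjusted p = 0.477 with an estimated correlation. Nuclear-encoded oxidative phosphorylation genes had a median of 0.24 (camera adjusted p = 2.58e-09, and adjusted p = 0.487 with an estimated correlation). None of their 68 members passed over all probe sets, where SdhB (0.40) and ND-B16.6 (0.47) had the smallest p, 14 rose adjusted over the list alone, and 25 rose with the paired block.

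Genes of G1/S and DNA replication had a median of 0.28, higher in G2/M (camera adjusted p = 0.0023, and adjusted p = 0.851 with an estimated correlation). RfC3 alone of 40 passed over all probe sets, 4 rose adjusted over the list alone, and 6 rose with the paired block. Genes of mtDNA maintenance and transcription had a median of 0.22 (camera adjusted p = 0.0166, and adjusted p = 0.487 with an estimated correlation), with none of 11 past the threshold, 1 adjusted over the list alone and mtTFB2 at 0.42. Mitochondrial aminoacyl-tRNA synthetase genes had a median of 0.11 (camera adjusted p = 0.0372, and adjusted p = 0.486 with an estimated correlation). MetRS-m rose by 0.58, as 1 of 14 (2 adjusted over the list alone), and the list was not called with the paired block (camera adjusted p = 0.0569).

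Lower in G2/M were antioxidant and xenobiotic defence genes (median -0.16, camera adjusted p = 8.36e-05, and adjusted p = 0.477 with an estimated correlation). The member that passed over all probe sets was Sod2, the mitochondrial superoxide dismutase gene, which rose by 0.39, against the list. Adjusted over the list alone 1 rose and 1 fell, and 7 fell with the paired block. Copper and metal response genes had a median of -0.21 (camera adjusted p = 0.0011, and adjusted p = 0.477 with an estimated correlation), and MtnD fell by 0.50, as 1 of 9 (2 adjusted over the list alone). Immune response genes had a median of -0.12 (camera adjusted p = 0.0142, and adjusted p = 0.487 with an estimated correlation) with none of 18 past the threshold. Autophagy genes had a median of -0.09 (camera adjusted p = 0.0451, and adjusted p = 0.879 with an estimated correlation), also with none of 20. Heat shock protein genes (median -0.37) were not called without a block (camera adjusted p = 0.109) and were called with the paired block (camera adjusted p = 0.0178, and adjusted p = 0.431 with an estimated correlation). The median and the test differed in sign for p53 and DNA damage genes and for mitochondrial import and dynamics genes, and neither list was called.

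In libraries labelled knockdown, the same comparison of phases gave changes of similar size, none past the threshold without a block. CG31125 was 1.66 ± 0.17 (SE) higher in G2/M, the dystrobrevin gene Dyb 1.45 higher, CG4570 1.52 higher, Boot 1.16 higher and the kinase gene Mos 1.17 higher, and these were the 5 smallest p-values. The adjusted p was 0.0520 for CG31125 and Dyb and up to 0.0932 for Mos in limma. CG31125 read 7.16 ± 0.05 (SD, n = 2) in G1 and 8.82 ± 0.15 (SD, n = 2) in G2/M. The mitotic genes ncd and CycB3 gave 2.08 and 1.30.

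Limma called 0 probe sets between phases in knockdown, with 1724 at an unadjusted p under 0.05. With culture as a paired block 315 passed (148 higher, 167 lower), of which 301 also passed in control with the block and in the same direction, against 14.1 for independent lists. Both lists came from 1 fit and share each probe set's variance estimate, so they are not independent and 14.1 is no fair baseline. Across probe sets the phase differences in control and in knockdown correlated at r = 0.794 (rho = 0.616). No probe set passed the interaction, which is the test of their difference. Both labels hold cultures with high and with low Slimp signal, so the interaction does not compare those kinds of culture.

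Camera called 9 lists in knockdown. G2/M and mitosis genes had a median of 0.47 (adjusted p = 2.88e-26, and adjusted p = 0.532 with an estimated correlation), with 38 of 65 higher adjusted over the list alone and 17 with the paired block. Mitochondrial ribosomal protein genes had a median of 0.26 (adjusted p = 3.69e-15, and adjusted p = 0.532 with an estimated correlation). Oxidative phosphorylation genes had a median of 0.23 (adjusted p = 5.24e-10, and adjusted p = 0.540 with an estimated correlation). The median was 0.27 for G1/S and DNA replication genes (adjusted p = 0.000213, and adjusted p = 0.676 with an estimated correlation) and 0.18 for mtDNA genes (adjusted p = 0.0150, and adjusted p = 0.540 with an estimated correlation). It was 0.12 for mitochondrial aminoacyl-tRNA synthetase genes (adjusted p = 0.0175, and adjusted p = 0.532 with an estimated correlation), a call lost with cyclic loess (0.0751). Copper response genes (median -0.17, adjusted p = 0.0150), immune genes (median -0.21, adjusted p = 0.0214) and antioxidant genes (median -0.13, adjusted p = 0.0436) were lower. Those 3 had an adjusted p = 0.532, adjusted p = 0.540 and adjusted p = 0.676 with an estimated correlation, and the antioxidant call was lost with replicate number as a replicate block (0.0535). With the paired block, camera also called the proteasome (median 0.10, adjusted p = 0.0117) and heat shock protein genes (median -0.41, adjusted p = 0.00122), which gave adjusted p = 0.622 and adjusted p = 0.535 with an estimated correlation. The median and the test differed in sign for mitochondrial chaperone and ATF4 genes, neither of them called.

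Phase was last compared over all 5 cultures at once, with culture as a paired block. The genotype labels enter only through the pairing of libraries, so an exchange of whole cultures leaves the result unchanged. The 6 libraries labelled control are part of this comparison, so it is no independent repeat of the control contrast. NANS rose 5.22-fold (log2 2.38 ± 0.07 SE), ncd 4.05-fold (log2 2.02 ± 0.08 SE) and Sirt4 3.64-fold. Phyhd1, which encodes a protein with a phytanoyl-CoA dioxygenase domain, rose 4.16-fold, CG10508 3.49-fold, CG15653 3.42-fold and CG31125 3.12-fold. SecS rose 2.95-fold, the mitochondrial ubiquitin ligase gene Mul1 2.79-fold and RfC3 2.67-fold.

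The largest falls over all 5 cultures were those of CanB at 3.03-fold and the metallothionein gene MtnB at 2.99-fold (log2 -1.58 ± 0.11 SE). CG31272 fell 2.69-fold, CG8620 2.62-fold, Obp49a 2.55-fold and Srg2 2.44-fold. The glutathione S-transferase gene GstD6 fell 2.39-fold, Ugt37D1 2.23-fold, CG15347 2.22-fold and Rcd2 2.12-fold. The adjusted p of these 20 genes lay between 1.68e-06 and 0.00175 in limma. Each lay on the same side in all 5 cultures, which the naming rule of no overlap forces. SerRS-m was 0.28 ± 0.06 (SE) higher in G2/M (adjusted p = 0.0135 in limma), and Slimp did not pass. The metallothionein MtnD fell by 0.50, from a mean of 13.24 to 12.75.

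**Figure D2:**
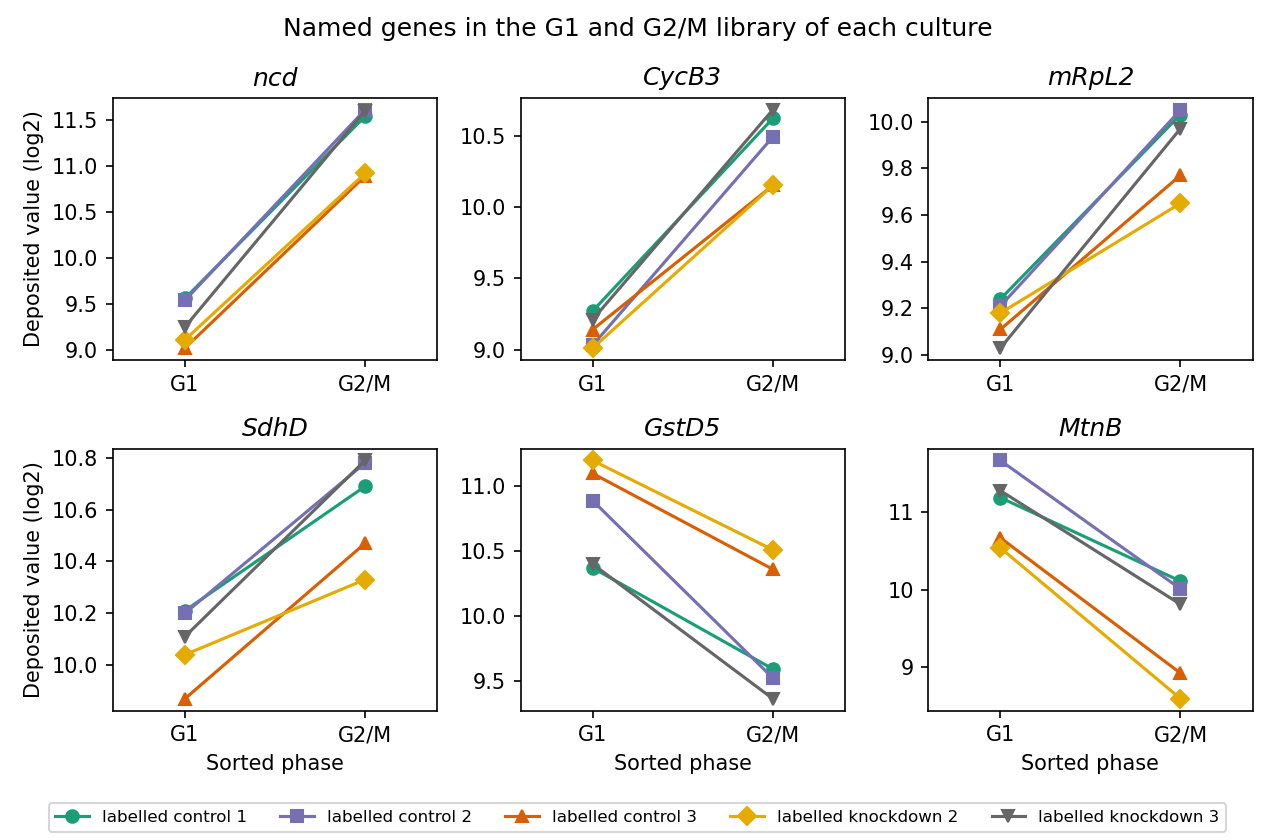
Deposited log2 values of 6 genes in G1 and G2/M, with 1 line per culture joining its 2 libraries and each panel on its own scale. In all 5 cultures ncd, CycB3, mRpL2 and SdhD lie higher in G2/M, and GstD5 and MtnB lie lower.

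In total 3623 probe sets passed in limma, 1933 higher and 1690 lower in G2/M, and 86 of them changed by at least 1 on the log2 scale. The count ranged from 2189 (without control 2) to 3414 (without control 3) when 1 culture was left out, and was 1586 without control 3 and knockdown 3. Which direction had more calls depended on the scaling, with 1657 higher and 2114 lower after cyclic loess and 2273 higher and 1515 lower after median centring. All 169 probe sets called in control, whose libraries both counts share, were among the 3623 in the same direction.

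Most genes of the mitotic list rose, with 47 of 65 higher and none lower (50 and 1 adjusted over the list alone) and a median of 0.46. Culture medians were lower in the cultures with the higher Slimp signal, at 0.25 in control 3 and 0.30 in knockdown 2. They were 0.56 in control 1, 0.62 in control 2 and 0.64 in knockdown 3. This difference between cultures was seen after the fact and was not tested. Camera gave an adjusted p of 1.96e-19, and adjusted p = 0.316 with an estimated correlation. Examples were CycB3 (1.29), Ndc80 (1.09) and fzy (1.06). Of the G1/S and DNA replication genes 20 of 40 rose and 3 fell, or 22 and 4 adjusted over the list alone (median 0.25, camera adjusted p = 5.81e-05, and adjusted p = 0.612 with an estimated correlation). RfC3 (1.41), the origin recognition gene Orc5 (0.95), Cdc6 (0.83) and the DNA polymerase alpha subunit gene PolA2 (0.63) rose. RnrL, PCNA and Cdk4, chosen after their values were seen, fell. Culture medians of this list were 0.05 in knockdown 2 and 0.08 in control 3, against 0.21 in control 1, 0.59 in control 2 and 0.45 in knockdown 3.

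Of mitochondrial ribosomal protein genes 58 of 79 rose and 3 fell (65 and 3 adjusted over the list alone), with a median of 0.27 and culture medians from 0.22 to 0.31 (camera adjusted p = 1.96e-19, and adjusted p = 0.316 with an estimated correlation). mRpS14 (0.83), mRpL2 (0.74), mRpL49 (0.70) and mRpL9 (0.69) led them. Of oxidative phosphorylation genes 42 of 68 rose and 1 fell, or 49 and 2 adjusted over the list alone (median 0.24, culture medians from 0.18 to 0.30, camera adjusted p = 3.59e-12, and adjusted p = 0.316 with an estimated correlation). Examples were the succinate dehydrogenase gene SdhD (0.53) and the complex I genes ND-B14.5A (0.50), ND-18 (0.47) and ND-B14.5B (0.46). Of mtDNA maintenance and transcription genes 6 of 11 rose, or 7 adjusted over the list alone (median 0.22, camera adjusted p = 0.00682, and adjusted p = 0.476 with an estimated correlation), among them mtTFB2 (0.41) and the mitochondrial DNA polymerase gene PolG1 (0.39).

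Of mitochondrial aminoacyl-tRNA synthetase genes 6 of 14 rose (also 6 adjusted over the list alone), led by AsnRS-m (0.60) and MetRS-m (0.51), with a median of 0.11 (camera adjusted p = 0.0341, and adjusted p = 0.316 with an estimated correlation). That call was lost with cyclic loess (adjusted p = 0.0753) and without control 1 (0.0501) or control 3 (0.0573). Cytosolic aminoacyl-tRNA synthetase genes had 0 higher and 3 lower of 18, ValRS (-0.30), TyrRS (-0.22) and CysRS (-0.18), and were not called as a list (median -0.03, camera adjusted p = 0.307). Mitochondrial chaperone and protease genes (3 higher, 1 lower of 19, median 0.01, camera adjusted p = 0.847) and import and dynamics genes (2 higher, 1 lower of 17, median 0.03, camera adjusted p = 0.565) were not called. Pink1 (0.51) rose and the transport adaptor gene milt (-0.47) fell in those lists.

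Camera called 4 lists lower in G2/M. Antioxidant and xenobiotic defence genes had 10 lower and 1 higher of 21, or 12 and 2 adjusted over the list alone (median -0.16, camera adjusted p = 0.000116, and adjusted p = 0.316 with an estimated correlation), with GstD5 (-0.92), GstD2 (-0.73), Cyp6a2 (-0.70) and the glutathione synthesis gene Gclc (-0.66). Copper response genes had 4 lower of 9, or 7 adjusted over the list alone (median -0.21, camera adjusted p = 0.00108, and adjusted p = 0.316 with an estimated correlation), including MtnB, MtnD and the zinc transporter gene ZnT35C (-0.78). Immune genes had 8 lower and 1 higher of 18, or 10 and 1 adjusted over the list alone (median -0.15, camera adjusted p = 0.00108, and adjusted p = 0.316 with an estimated correlation), led by pirk (-0.93) and AttD (-0.69). Heat shock protein genes had 3 lower of 5, also 3 adjusted over the list alone (median -0.39, camera adjusted p = 0.00622, and adjusted p = 0.316 with an estimated correlation), Hsp26 (-0.50), stv (-0.48) and DnaJ-1 (-0.39). Of the 18 genes of that list only 5 were measured, and the family of genes named Hsp, described below, was not called.

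**Figure D3:**
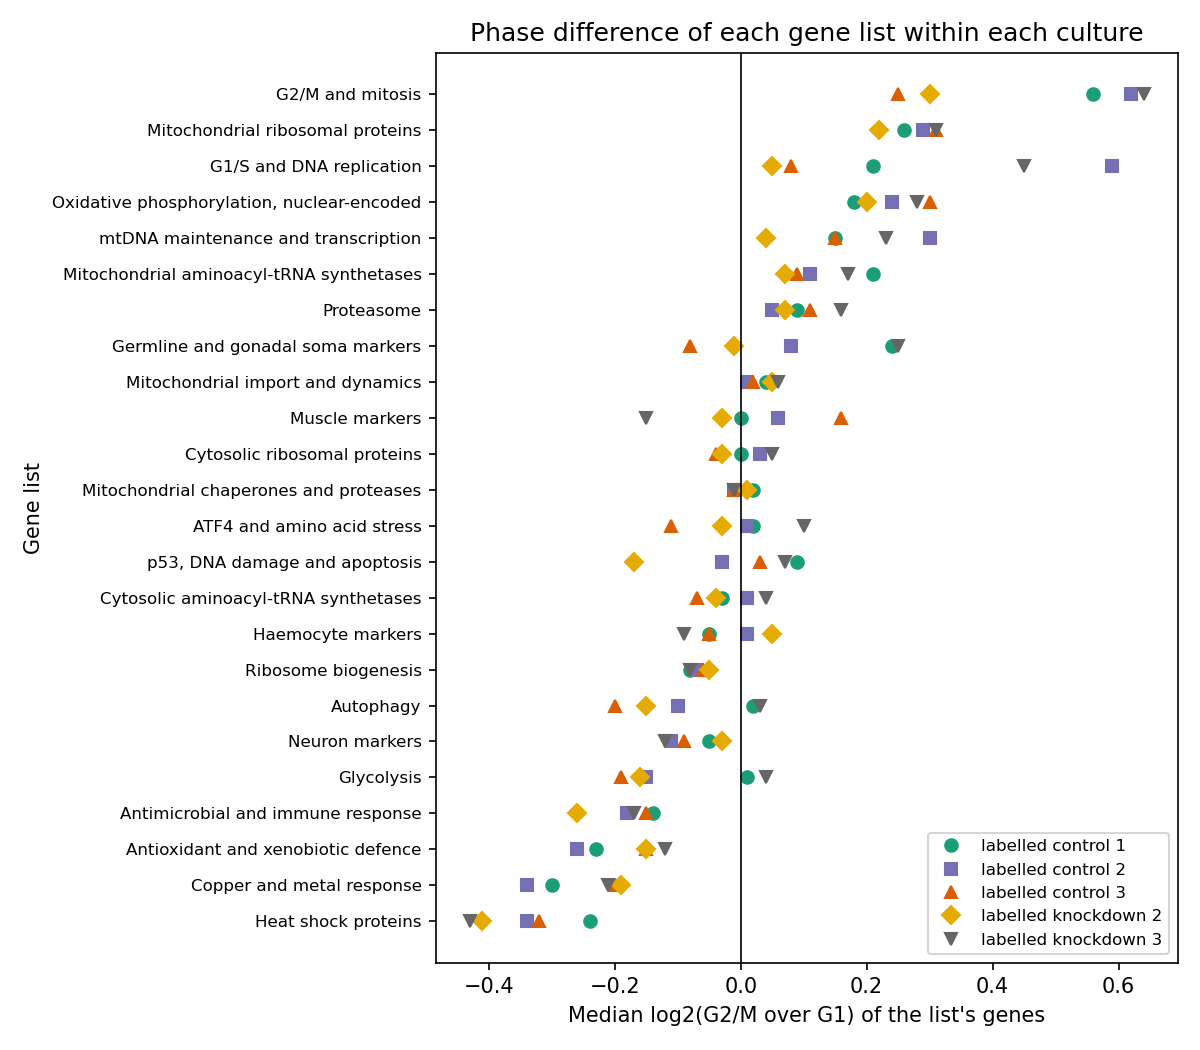
Median log2 difference between G2/M and G1 over the genes of each of 24 lists, with 1 point per culture. In all 5 cultures the points of the mitotic list (0.25 to 0.64) and of the mitochondrial ribosomal protein list (0.22 to 0.31) lie above 0. Those of the 5 measured heat shock protein genes (-0.43 to -0.24) lie below 0.

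Proteasome genes had 9 higher of 40 (11 higher and 2 lower adjusted over the list alone), such as Rpt3R (0.27) and Rpn12 (0.26), with a median of 0.09 (camera adjusted p = 0.0335, and adjusted p = 0.612 with an estimated correlation). The call was lost without knockdown 2 (0.0766), control 3 (0.0900) or knockdown 3 (0.0640). Autophagy genes had 3 lower and 1 higher of 20 (median -0.07, camera adjusted p = 0.0816). Glycolysis genes had 4 lower, such as Tpi (-0.45), and 1 higher of 10 (median -0.13, camera adjusted p = 0.105). Ribosome biogenesis genes had 1 lower and 1 higher of 17 (median -0.08, camera adjusted p = 0.105). With cyclic loess the autophagy (0.0314) and ribosome biogenesis (0.0382) lists were called lower, and neither was with an estimated correlation (adjusted p = 0.612 and adjusted p = 0.316). Autophagy was also called lower without knockdown 3 (0.0244). Cytosolic ribosomal protein genes had 1 higher of 34 (median -0.01, camera adjusted p = 0.814). In the list of p53, DNA damage and apoptosis genes 6 rose and 5 fell of 19 (median -0.01, camera adjusted p = 0.725). The Chk2 kinase gene lok rose by 0.86, and the caspase gene Dronc (-0.59) and the end-joining genes Irbp (-0.56) and Ku80 (-0.39) fell. ATF4 and amino acid stress genes had 3 higher and 4 lower of 18 (median -0.04, camera adjusted p = 0.677), with Sesn at 0.48 and trbl at -0.37.

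Markers of cell types were lists of another kind. Haemocyte markers had 2 higher and 3 lower of 25 (median -0.04, camera adjusted p = 0.426), with the scavenger receptor gene Sr-CI at -0.78 and the peroxidasin gene Pxn at 0.34. Neuron markers had none past the threshold of 12 (median -0.07, camera adjusted p = 0.105), where brp was at -0.16 and ChAT at -0.18. Muscle markers had 1 higher of 13, Act79B at 0.19 (median -0.03, camera adjusted p = 0.847). Germline and gonadal soma markers had 3 higher and 1 lower of 12, with piwi at 0.37 and osk at -0.54 (median 0.12, camera adjusted p = 0.350).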

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

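The removal of cultures, the crossed block, the phase contrast over all 5 cultures and the culture block for lists were chosen after the data were examined, and the other settings before. Where not stated, the cause of a shift was not tested. No gene named by its p or fold and no called list changed direction in any setting run. For phase genes past the threshold, the rule of no overlap forces this when libraries are left out. The culture block and the eBayes settings leave their estimates unchanged. Slimp and SerRS-m did change direction between the genotype labels when libraries or cultures were left out. Slimp ranged from -1.43 to 3.71 in G1, -1.19 to 3.55 in G2/M, -1.31 to 3.63 averaged and -1.89 to 2.02 for the interaction. SerRS-m ranged from -0.17 to 0.11, -0.22 to 0.03, -0.11 to 0.04 and -0.24 to 0.11. Of the comparisons of named genes with a setting, the control phase contrast kept its call in 332 and lost it in 224, and the knockdown phase contrast gained a call in 28. The counts for knockdown against control in G1, in G2/M, averaged and for the interaction were 0 in limma in every setting run (unadjusted p under 0.05 for 482, 164, 267 and 333), except that without the cultures labelled control 3 and knockdown 3 they were 363, 131 and 861 for the first 3, with the spread from control libraries alone, and 436 for the average with each culture averaged to 1 value. Leaving out each library or culture gave 0 for these 4.

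For phase in control, the 169 probe sets became 311 without the dimmer probe sets (fewer tests), 837 with array weights, 74 with only the groups compared, 45 at a log2 change of at least 1, and 481 without control 3 and knockdown 3 or without control 3 and knockdown 2. With replicate number as a replicate block the count was 0 in limma (2655 at an unadjusted p under 0.05), with culture as a random replicate block 1325, with culture as a fixed replicate block 1678, and with the crossed replicate block 1254. Leaving out each library gave 0 to 213 and each culture 0 to 74, with 62 without control 3 and 74 without either knockdown culture. A lone remaining library was assumed to vary like the other groups.

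For phase in knockdown, the count of 0 became 2 without the dimmer probe sets, with cyclic loess, with median centring, with trend and robust eBayes and with 1 probe set per gene, and 3 without control 3 and knockdown 2. With culture as a random replicate block it was 160, as a fixed replicate block 315 and with the crossed replicate block 165. Leaving out each library gave 0 to 1 and each culture 0 to 5. Over all 5 cultures, the 3623 became 86 at a log2 change of at least 1, 1695 with no replicate block, 1586 without control 3 and knockdown 3, and 2189 to 3414 without each culture, including 2413 without knockdown 3. The consensus correlation within a culture was 0.409.

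Camera called 10 lists in control, 9 in knockdown and 11 over all 5 cultures. With an estimated correlation each became 0, with or without the paired culture block. Directional fry called 3, 0 and 12, and mixed fry 7 in control and 0 in knockdown. With replicate number as a replicate block camera called 1 list for knockdown against control in G2/M (heat shock, adjusted p = 0.0425) and 2 for the average (heat shock, adjusted p = 0.0123, and haemocyte markers, adjusted p = 0.0341), and 0 without it. With an estimated correlation and no block these gave an adjusted p of 0.916, 0.971 and 0.971. Leaving out each culture gave 9 to 11 lists over all 5 cultures. The correlation of the knockdown differences moved from 0.161 to 0.268 without the dimmer probe sets. No scaling moved the median of all probe sets by over 0.1. Signal over background was not analysed here, so changes of dim probe sets have no lower bound.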

Other observations

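The comparison of gene families, the culture values, and the tests of the label exchange, the shared batch, the copper induction the splits of the knockdown average and the culture means were chosen after the values they rest on were seen.

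Families of genes that share a symbol stem were compared between phases over all 5 cultures, with 76 families of at least 8 genes. Of mitochondrial families, camera called mRpL, mRpS and ND higher in G2/M (adjusted p = 3.98e-17, 3.83e-09 and 0.00028). With an estimated correlation their adjusted p was 0.661, 0.661 and 0.848. The families COX (median 0.11, camera adjusted p = 0.212) and Tim (median 0.03, camera adjusted p = 0.742) were not called. Nuclear pore genes named Nup had 14 of 20 higher and 2 lower in G2/M and a median log2 difference of 0.30 (camera adjusted p = 0.000205, and adjusted p = 0.848 with an estimated correlation). Nup35 (1.24), Nup205 (0.60), Nup75 (0.59) and Nup160 (0.52) led them. Camera also called 3 detoxification families lower. The glutathione S-transferase genes named GstD had 8 of 11 lower (median -0.44, camera adjusted p = 4.97e-05), those named GstE had 6 of 13 lower and 1 higher (median -0.18, camera adjusted p = 0.00995), and UDP-glycosyltransferase genes had 7 of 35 lower (median -0.08, camera adjusted p = 0.00961). With an estimated correlation the adjusted p was 0.848, 0.661 and 0.661. Receptor genes named mthl had 3 of 14 lower (median -0.12, camera adjusted p = 0.0486, and adjusted p = 0.661 with an estimated correlation). The 8 genes named Hsp had 1 lower and were not called (median -0.06, camera adjusted p = 0.317). GstD6 (-1.26), GstD5 (-0.92), Ugt302C1 (-0.78) and GstE11 (-0.65) were among those that fell.

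The probe sets with the largest SD between culture means (both phases averaged) were also listed, as values. Slimp ranked 1, against an SD of 1.97 for the next and a median of 0.0998 over all probe sets. In the order control 1, control 2, control 3, knockdown 2 and knockdown 3, as labelled, CG3397 read 5.08, 5.55, 8.87, 8.83 and 5.16. The ionotropic receptor gene Ir75a read 4.70, 4.69, 8.00, 8.13 and 4.63, the tetraspanin gene Tsp42Ec 6.27, 6.52, 9.10, 9.06 and 6.57, and the ligand gene mav 7.12, 7.20, 9.36, 9.48 and 7.04. CG11313 read 10.03, 10.06, 7.20, 7.60 and 9.93. Medians of the glycolysis list, relative to the mean of the 5 cultures, were -0.21, -0.15, 0.27, 0.38 and -0.24, and those of the G1/S and DNA replication list were 0.14, 0.13, -0.18, -0.16 and 0.07.

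Slimp and the whole arrays went against the genotype labels. Weaker copper induction in the cultures with low Slimp was set against metallothionein differences (knockdown 2 minus knockdown 3, and control 3 minus the mean of controls 1 and 2). Their median was -0.18, the upper quartile -0.08 and the lowest value -1.21 (MtnB), with 14 of 16 below 0, a bound set after the count was seen. These are 4 probe sets repeated over both phases and few cultures, and MtnA lay close to the array maxima. The values show no weaker induction in the cultures with low Slimp, but they cannot exclude it. Weaker induction in the cultures with high Slimp stays open. A batch shared by control 3 and knockdown 2 cannot be told apart. Slimp ranked 1 among 18769 probe sets, within the first 10 set as the bound. That bound was too weak, since CG3397 and Ir75a had nearly the same SD (1.97 and 1.86) and pattern. They are not the named target, but whether the construct or a loss of SLIMP acts on them was not tested. Deviations over whole arrays of control 3 and knockdown 2 correlated at 0.65 in G1 and 0.50 in G2/M. An exchange of the labels of control 3 and knockdown 3 remains a candidate explanation: of the 10 ways to put 2 cultures together, that of control 3 with knockdown 2 called 3860 probe sets in limma for the average over phases, the highest other called 1, and the labelled way called 0, or 2403, 0 and 0 with each culture averaged to 1 value (unadjusted p under 0.05 for 4971, at most 1763, and 94). Under that hypothesis the knockdown cultures would be those with the higher Slimp signal, and whether the probe set reads the RNA interference construct was not tested, so the biological effect of the knockdown stays open.

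For the knockdown average, the real count was 0, which all 100 splits of the arrays within phase must reach, so they decide nothing about chance. The highest other split, that of control 3 with knockdown 2, called 3860, which points to a structure of the samples. For phase in control, 10 splits of 6 arrays are too few for a share under 0.05, and 1 of them, the real one with 169, gave as many, with 0 for the highest other. For phase over all 5 cultures, 1 of 100 drawn splits, the real one, called as many as 3623, and the highest other called 1972, but most of these keep both libraries of some culture on 1 side. The splits that part all 5 cultures number 16, too few for a share under 0.05, and the highest other of them called 0.

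The higher level of mitochondrial genes in G2/M was weighed against a shift shared by all genes of like signal level. The median log2 difference of mitochondrial ribosomal protein genes (0.27) lay at percentile 100 of 10000 random lists matched on mean signal, whose highest median was 0.15. Oxidative phosphorylation genes (0.24) also lay at percentile 100, with 0.11 as the highest of the matched lists. Both argue against a level-dependent shift. Bias of the amplification by transcript length or base composition was not tested, and a difference between the phases themselves, which the design gives, stays open and may account for it.

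Genes called between phases may also change together with their neighbours on the chromosome. Among 11891 pairs of adjacent measured genes, 617 were called in the same direction (399 higher, 218 lower), against a median of 310 and a highest count of 377 in 10000 shuffles (1-sided permutation p = 1e-04, the smallest that they can give). Neighbouring genes were thus called together more often than shuffled genes. The shuffles were not matched on signal level, so they cannot tell shared changes from neighbours of like signal. Clusters of related genes such as GstD, overlapping transcripts and probes that read both neighbours stay open as sources, since none of them was tested.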
